A study of Mus musculus with 48 samples.

How the data were processed

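The deposited files held, for each of 48 arrays, a signal (the mean intensity of a probe type after the scanner software's summary), the number of beads, the spread between beads and a detection p-value per probe. The submitters' processing notes name BeadStudio, and the file headers name BSGX 3.2.7. The deposited series table held a second value per probe, which the authors give without units. These values had medians of 7.56 to 7.64 per array and ranked the probes of an array as the signal did (lowest Spearman rho 0.999999), so they were read as log2-like intensities compressed at the dim end. As deposited by the authors, these log2-like values had been normalized between arrays before deposit, to judge by their shared medians, and the method behind them is not given in the sources used here. Per the labels, RNA was extracted with Trizol and RNeasy columns, treated with DNase and turned into biotinylated cRNA. All main results start from the deposited signal and detection p-values. The 96 columns holding measures of spread were not used. Bead numbers entered no test and were only summarised.

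Signals were corrected for background with the normexp model of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values, then quantile normalized over all 48 arrays after adding an offset of 16 and set on a log2 scale. Of 25697 probes, 23681 were named through their Entrez identifier and 739 through a RefSeq accession, and 1277 kept the symbol in the file. This updated 4452 symbols. Where a gene had more than 1 probe, which held for 5013 of 18006 genes, the probe with the highest mean over all arrays stood for the gene. A gene was tested in a comparison when its detection p-value was under 0.05 on at least as many of the comparison's arrays as the smaller group has.

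Each comparison was fitted on its own with limma linear models and empirical Bayes moderation. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fixed lists of marker genes, 27 lists written from general knowledge before the data were examined, were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Lists with fewer than 3 measured genes were not tested, and list p-values were adjusted over the lists of a comparison. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the genes of 1 list only. The difference between the NP23 effects in marrow and thymus came from 1 model of the 12 arrays. That between thymus and spleen, which came from the same animals, used the animal as a block with an estimated correlation of 0.163. Differences between leukaemias in Hox genes and their cofactors were tested on 32 genes in 1 model.

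The genes named for each comparison were picked by a rule fixed before the data were examined. For each comparison they were drawn from the 10 largest rises and 10 largest falls among called genes detected on every array of the higher group, up to 4 genes of each list by smallest adjusted p, and always Hoxa5, Hoxa7, Hoxa9, Hoxa10, Hoxb5, Hoxb8, Meis1, Pbx3, Nup98 and Phf23. Clone names were skipped. Genes named as shared by AML, T-ALL and B-ALL, such as Camk2b, were taken from the shared calls and need not follow this rule. A gene not well above background on any array of its lower group is given as "at least N-fold". This bound sets the bright group's mean against, on each array, the higher of the lowest signal among probes well above background and the probe's own signal. The mouse Nup98 and Phf23 probes may not report the fusion transgene, so they check nothing about it.

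Alternatives tried were: no background correction, the authors' deposited values, scaling to the median only, no detection filter, detection p under 0.01, every probe tested, all groups in 1 fit, moderation with a trend and robust priors, array weights, leaving out each array in turn, adding the lymph node AML or the spleen and lymph node T-ALL samples, B-ALL from lymph node only, no animal block, and camera with an estimated correlation. A term for sex read from the Y-linked Eif2s3y and Kdm5d (both at a detection p under 0.01), a term for sex read from Xist (below or above 7.61, the midpoint of its range), the removal of genes on X and Y, median scaling for the lists, the removal of the 2 dimmest marrow arrays, and an animal block and other settings for the Hox differences were added after seeing the data. A slide effect could not be fitted because the files give no slide.

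The methods were tested on simulated data, drawn as independent normal values with each gene's measured mean and spread, in which 200 genes were shifted, 100 by 1 and 100 by 2 log2. The shares recovered were 63% and 88% for AML against wild-type marrow, 34% and 82% for T-ALL against wild-type thymus, and 50% and 79% for B-ALL. They were 40% and 84% for NP23 marrow, 62% and 89% for NP23 thymus, 76% and 96% for NP23 spleen, and 15% and 60% for the lines. AML against NP23 marrow gave 64% and 89%, T-ALL against NP23 thymus 50% and 78%, the marrow and thymus difference 30% and 84%, and the thymus and spleen difference 51% and 86%. False calls in the same order numbered 9, 7, 6, 6, 8, 16, 4, 12, 7, 7 and 6. Of the lists, 11 of 11 shifted by 1 log2 were called, and 0 of 286 left unshifted. The simulated genes of a list varied independently. These counts therefore tell nothing about lists whose genes vary together, such as megakaryocyte genes in NP23 spleen (estimated correlation 0.905).

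Samples with conflicting or single labels were left out of the comparisons: 1 lymph node sample titled AML whose disease field reads B-ALL, and 1 spleen sample labelled erythroid. The 2 lymph node AML, the 1 spleen T-ALL and the 1 lymph node T-ALL samples entered only the alternatives. Several genes of the fixed lists, Kit, Mki67, Cd79a and Igll1 among them, had no matching probe and were not analysed here. The sample titles carry a different number for each sample of a compared group, read here as the animal, so the p-values measure the spread between these animals, or between 2 lines.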

Results

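Gene expression was measured in 48 samples of mouse blood-forming tissue, leukaemia and cell lines on Illumina bead arrays of 25697 probes. NP23 mice carry a transgene joining NUP98, a nuclear pore gene, to PHF23, which encodes a PHD finger protein. The groups compared were AML in marrow (n = 10), T-ALL in thymus (n = 8), B-ALL (n = 4, 3 from lymph node and 1 from marrow), healthy NP23 marrow, thymus and spleen (n = 3 each), wild-type marrow, thymus and spleen (n = 3 each) and 2 lymphoblastic T cell lines. The median probe signal of an array lay between 82.1 and 147, and 44.2% to 56.2% of probes were detected at a detection p under 0.05. Pearson r between arrays over all genes was 0.958 to 0.987 within AML, 0.916 to 0.974 within T-ALL, 0.946 to 0.965 within B-ALL and 0.981 to 0.996 within the 6 healthy groups. Wild-type thymus and spleen came from the same 3 animals, as did NP23 thymus and spleen, and animal J5 gave both an AML and a T-ALL sample.

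The first comparison asked how AML marrow differs from wild-type marrow. Hoxa5, a homeobox gene active in early blood progenitors, rose by 5.56 log2 (SE 0.20, adjusted p = 6.9e-11), from 5.79 (SD 0.31) in 3 wild-type arrays to 11.34 (SD 0.31) in 10 AML arrays. Its wild-type signal was close to background (detection p 0.035, 0.030 and 0), so this size is not exact. Hoxa7 rose by 4.55 (SE 0.17, adjusted p = 1.1e-10), and Hoxa9, not well above background in wild-type marrow, was at least 17.4-fold higher (adjusted p = 1.8e-11). Red cell genes were among the largest falls: Alas2, the first enzyme of erythroid haem synthesis, fell by 8.41 (SE 1.06, adjusted p = 4.0e-05), and Trim10, a RING finger gene of red cell precursors, fell by 8.25 (SE 0.28, adjusted p = 3.6e-11). Of 10478 genes tested with limma, 3282 were called at a Benjamini-Hochberg adjusted p under 0.05, 1897 higher and 1385 lower. At least 2-fold rises numbered 541 and falls 825.

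Of the 9 Hoxa genes tested, 6 rose, also 6 adjusted over the list alone, with a median of 2.24 log2 (camera adjusted p = 2.7e-06, and 0.00686 with an estimated correlation). Hoxa2 (2.39) was among them, as was Hoxa10, at least 2.99-fold higher. None of the 7 Hoxb genes was called, nor was the list (median 2.0, camera adjusted p = 0.246). Hoxb5 stood at 8.28 with an SD of 2.36 across AML arrays (log2 change 2.69, adjusted p = 0.12). Meis1, the usual partner of Hoxa9, rose by 2.37 (SE 0.31, adjusted p = 5.6e-05), while Pbx3 (0.34, adjusted p = 0.56) did not. Hoxb8 was below detection and was not tested. Nup98 did not change (0.22, adjusted p = 0.23), and Phf23 rose by 0.90 (adjusted p = 0.015). Beyond the Hox genes, the largest rises were Nkx2-3, a homeobox gene of gut and spleen development (5.70, SE 0.68), Gpnmb, a glycoprotein of macrophages and melanocytes (5.67, SE 0.59), and the bicarbonate transporter Slc4a8 (4.78, SE 0.43). The dipeptidase gene Dpep2 (4.19) and the endothelin receptor gene Ednrb (3.92) also rose, and the kallikrein Klk1b11 was at least 18.9-fold and coagulation factor F7 at least 14.1-fold higher.

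The erythroid list fell: 17 of 18 genes, 18 adjusted over the list alone, with a median of -5.09 (camera adjusted p = 3.1e-23, and 0.00686 with an estimated correlation). The anion exchanger Slc4a1 (-7.86, SE 1.0), the haemoglobin chaperone Eraf (-7.90, SE 0.85) and the erythroid regulator Klf1 (-5.52, SE 0.24) were examples. Outside the list, the blood group gene Kel was at least 83.5-fold lower. Of 12 mature B cell genes 10 fell, 11 adjusted over the list alone (median -2.53, camera adjusted p = 2.5e-10, and 0.00303 with an estimated correlation), with the kinase Blk at -4.77. Of 9 precursor B genes 4 fell and 1 rose (median -1.32, camera adjusted p = 0.036, and adjusted p = 0.355 with an estimated correlation), with the surrogate light chain genes Vpreb3 at -6.50 (SE 0.21) and Vpreb1 at -3.58. Of 9 megakaryocyte genes 8 fell (median -2.03, camera adjusted p = 4.7e-05), among them the platelet glycoprotein genes Gp5 (-2.76) and Gp9 (-2.38); the adjusted p was 0.397 with an estimated correlation. The late neutrophil list fell (4 of 15 genes, median -1.69, camera adjusted p = 0.00158), with Cxcr2 (-3.43) and Mmp9 (-3.12), and its adjusted p was 0.734 with an estimated correlation. The eosinophil ribonuclease Ear6 was at least 127-fold lower, and Prss34, a protease of mast cells and basophils, fell by 7.34.

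Cell cycle genes fell in AML, 13 of 21 and 14 adjusted over the list alone (median -0.74, camera adjusted p = 7.0e-07, and adjusted p = 0.355 with an estimated correlation). Rrm2 (-1.40, SE 0.23), Birc5 (-1.12, SE 0.15) and Cdk1 (-1.04, SE 0.13) were examples. Interferon genes (2 of 17 fell, median -0.77, camera adjusted p = 0.0286, and adjusted p = 0.831 with an estimated correlation) included Rsad2 (-5.51) and Isg15 (-3.50). Notch targets (4 of 10 fell, median -0.43, camera adjusted p = 0.0411, and adjusted p = 0.42 with an estimated correlation) included Nrarp (-2.05) and Hes1 (-0.69). Macrophage genes moved both ways: Cd68 (1.79) and Adgre1 (1.45) rose with 2 others, Spic (-3.67) and Vcam1 (-3.65) fell with 2 others, and the list was not called (camera adjusted p = 0.527). Of 11 primary granule genes 2 rose, Ctsg (0.93) and Gstm1 (1.28), and the list was not called (camera adjusted p = 0.962). Among 14 stem and progenitor genes Cd34 (1.89) and Cd93 (1.70) rose and 2 fell, with a positive median (0.25), a negative mean (-0.24) and no list call (camera adjusted p = 0.962). Of 12 p53 targets 5 rose, Ccng1 (0.89) among them, and 2 fell, Gadd45a (-4.33) among them (camera adjusted p = 0.51). The plasma cell list (median 0.75, mean -0.14), the Meis and Pbx list and the Hoxc and Hoxd list also had signs that differed between median, mean and test, and none was called.

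The AML count moved when single controls were left out: 1965 genes were called without wild-type marrow replicate 2 and 2104 without replicate 3, against 3282. With array weights it rose, as given under processing. Scaling to the median gave 2855 rises and 1037 falls in place of 1897 and 1385, with a median over all genes of 0.27 log2 instead of 0.12.

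The second comparison asked how T-ALL thymus differs from wild-type thymus. Hoxa7 rose by 3.49 log2 (SE 0.26, adjusted p = 1.0e-05), from 7.48 (SD 0.14) in 3 wild-type to 10.97 (SD 0.44) in 8 T-ALL arrays, and Hoxa9 rose by 3.45 (SE 0.25, adjusted p = 9.8e-06). Hoxa9 was close to background in wild-type thymus (detected on 2 of 3 arrays), so its size is not exact. Arg1, the arginase of activated macrophages, rose by 4.16 (SE 0.83, adjusted p = 0.0052). Keratin and fat cell genes fell: Krt18, a keratin of thymic epithelium, fell by 4.41 (SE 0.50, adjusted p = 0.00015), and Scd1, a fatty acid desaturase, fell by 5.85 (SE 0.89, adjusted p = 0.001). Of 10998 genes tested with limma, 2070 were called at a Benjamini-Hochberg adjusted p under 0.05, 832 higher and 1238 lower, and 249 rose and 903 fell at least 2-fold.

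Of 8 Hoxa genes 4 rose, 5 adjusted over the list alone (median 1.53, camera adjusted p = 0.00042, and adjusted p = 0.381 with an estimated correlation). Hoxa5 rose by 2.57 (SE 0.30) from a wild-type level of 8.41, and Hoxa10 was at least 2.05-fold higher. Meis1 was not called (-1.03, SE 0.98, adjusted p = 0.48), and its level in T-ALL spread widely (7.98, SD 1.84). Its relative Meis2 fell by 2.66 (SE 0.33), Pbx3 rose by 1.41 (SE 0.32), Nup98 rose by 0.64 (adjusted p = 0.033), Phf23 (0.28, adjusted p = 0.33) and Hoxb5 (0.17, adjusted p = 0.58) were not called, and Hoxb8 was not tested. Hoxd8 fell by 0.97 (adjusted p = 0.047), and Hoxc6 was at least 1.98-fold lower (adjusted p = 0.00016). Other large rises were the gluconeogenic enzyme Fbp1 (3.99, SE 1.12), the mitochondrial dehydrogenase Aldh1b1 (3.47, SE 0.98), Gpnmb (3.04, SE 0.34), the growth factor Bmp7 (2.99, SE 0.33), the homeobox gene Hhex (2.97, SE 0.80) and the helix-loop-helix gene Olig3 (2.91, SE 0.45). Greb1 was at least 7.70-fold higher.

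Of 9 thymic epithelium genes 8 fell, 9 adjusted over the list alone (median -3.69, camera adjusted p = 5.8e-08, and adjusted p = 0.366 with an estimated correlation). Ccl25, which draws thymocyte precursors (-5.09, SE 0.63), the epithelial regulator Trp63 (-4.11, SE 0.50) and Krt8 (-3.69, SE 0.39) were examples. Tbata, also a gene of thymic epithelium, had the largest fall (-7.58, SE 1.04). It stood at 4.70 to 5.57 on the T-ALL arrays other than replicate 7 (10.6). This size rests on dim signals and is not exact. Of 9 adipocyte genes 8 fell, 9 adjusted over the list alone (median -3.01, camera adjusted p = 1.1e-07, and adjusted p = 0.366 with an estimated correlation), with leptin, Lep (-4.88, SE 0.69), and the lipase Lpl (-2.67, SE 0.35). Cidea (-6.14, SE 0.91) and Cox8b (-6.11), both typical of brown fat, Dgat2 (-5.89), Thrsp (-5.83) and Car3 (-5.59) were among the 10 largest falls.

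Myc rose by 1.74 (SE 0.26, adjusted p = 0.00096). In the list of nucleolar and Myc target genes, which counts Myc itself, 5 of 15 rose, 8 adjusted over the list alone (median 0.71, camera adjusted p = 0.00042, and adjusted p = 0.898 with an estimated correlation). Cad (1.37), Bop1 (1.04) and Nhp2 (1.04) were among them. Of 12 Notch targets Hes1 (2.28, SE 0.49) and Myc rose and Hey1 fell by 3.33 (SE 0.32), and the list was not called (camera adjusted p = 0.28). None of 17 T cell genes was called (median -0.43, camera adjusted p = 0.28). Of 13 cortical thymocyte genes 3 fell, with Satb1 at -1.49 (SE 0.29) and Cd4 at -1.68 (adjusted p = 0.049), and the list was not called (median -1.49, camera adjusted p = 0.0811). T-ALL replicate 4 stood apart, with a mean log2 signal of 7.02 over this list against 9.15 to 10.9 on the other T-ALL arrays. None of 21 cell cycle genes was called (median 0.33, camera adjusted p = 0.43). Replicate 4 had a mean log2 signal of 8.42 over this list. The other T-ALL arrays had 9.81 to 10.7, and wild-type thymus 9.79 to 9.93. Of 17 macrophage genes only Cd68 rose (1.45), and the list median was 0.17 (camera adjusted p = 0.946). Of 13 erythroid genes 5 fell, Alas2 (-4.93) the furthest, and 1 rose. The T-ALL lists for Hoxc and Hoxd, Meis and Pbx, and precursor B genes differed in sign between median, mean and test and were not called.

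Eif2s3y and Kdm5d, both on the Y chromosome, were both detected on 3 of 3 wild-type thymus arrays and on 1 of 8 T-ALL arrays, replicate 4, and Eif2s3y fell by 5.73. Xist was low on 3 of 3 and 3 of 8. T-ALL replicates 2 and 3 had low Xist (6.57 and 5.78) without Eif2s3y (4.51 and 4.45), so low Xist need not mark a male. Replicate 2 came from animal J5, whose AML array, replicate 9, had Xist at 9.30. With a term from Xist, added after seeing the data, 1442 genes were called, and Fbp1, Aldh1b1, Hhex, Hoxa10, Pbx3, Nup98 and Hoxd8 were not among them. These losses cannot be read as effects of sex. The count was 739, 933 and 818 without wild-type thymus replicates 1, 2 and 3, against 2070, 2956 without T-ALL replicate 4, and 4403 with array weights.

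The third comparison asked how B-ALL differs from wild-type spleen, a tissue from which none of the 4 B-ALL samples came. Vpreb1, part of the surrogate light chain of precursor B cells, rose by 8.24 log2 (SE 0.26, adjusted p = 2.8e-06), from 5.63 (SD 0.43) in 3 spleens to 13.87 (SD 0.31) in 4 B-ALL arrays. Rag1, which cuts immunoglobulin genes for joining, rose by 4.62 (SE 0.53, adjusted p = 0.00054), and Hoxa7 by 5.33 (SE 0.36, adjusted p = 4.6e-05). Fcer2a, the low-affinity IgE receptor of mature B cells, fell by 5.21 (SE 0.22, adjusted p = 7.4e-06), and Cd3g, part of the T cell receptor complex, fell by 5.94 (SE 0.26, adjusted p = 8.4e-06). Of 10519 genes tested with limma, 4208 were called at a Benjamini-Hochberg adjusted p under 0.05, 1980 higher and 2228 lower, and 1026 rose and 1611 fell at least 2-fold.

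Of 7 Hoxa genes 6 rose, also 6 adjusted over the list alone (median 2.13, camera adjusted p = 0.00024, and adjusted p = 0.409 with an estimated correlation). Hoxa5 rose by 3.53 (SE 0.51), Hoxa9 was at least 15.4-fold and Hoxa10 at least 3.08-fold higher, and Meis1 rose by 1.70 (SE 0.42, adjusted p = 0.016). Hoxb5 was spread over the 4 arrays (8.51, SD 3.01) and not called (2.28, adjusted p = 0.26), nor was the Hoxb list of 5 genes (median 1.0, camera adjusted p = 0.577). Meis2 fell by 2.11, Nup98 rose by 0.67 (adjusted p = 0.015), Phf23 was not called (-0.23, adjusted p = 0.38), and Pbx3 and Hoxb8 were not tested. Bahcc1, a BAH domain chromatin gene, rose by 5.43 (SE 0.18, adjusted p = 3.1e-06). Other large rises were the ribonuclease Rnase12 (8.24, SE 0.46), the decarboxylase Ddc (6.69, SE 0.26), and Crhbp and Tmem132e, at least 51.8-fold and 57.6-fold higher. Myl10, a myosin light chain gene, was at least 41.8-fold higher on average with an SD of 3.29.

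Of 13 precursor B genes 10 rose, 12 adjusted over the list alone (median 2.72, camera adjusted p = 5.6e-07, and adjusted p = 0.291 with an estimated correlation), with Vpreb3 (4.30, SE 0.28) and the B lineage factor Ebf1 (2.72, SE 0.17). Of 21 cell cycle genes 8 rose, 8 adjusted over the list alone (median 1.09, camera adjusted p = 0.00154, and adjusted p = 0.626 with an estimated correlation), with the helicase subunit Mcm7 (2.89, SE 0.16), Tyms (2.23) and Ccnb1 (2.12). Ezh2, the histone methyltransferase, rose by 2.90 (SE 0.25). Myc rose by 1.67. In the Myc target list, which counts Myc itself, 6 of 15 genes rose (median 0.50, camera adjusted p = 0.0344, and adjusted p = 0.626 with an estimated correlation), Nhp2 (1.5) among them. All 10 MHC class II genes fell (median -4.42, camera adjusted p = 1.2e-06, and adjusted p = 0.409 with an estimated correlation), with H2-Eb1 (-5.98, SE 0.49), H2-Aa (-5.18) and their activator Ciita, at least 37.3-fold lower. Of 13 mature B cell genes 7 fell and 3 rose (median -1.70, camera adjusted p = 0.0127, and adjusted p = 0.464 with an estimated correlation), with Ms4a1, which encodes CD20 (-3.95, SE 0.19), and the complement receptor Cr2, at least 16.5-fold lower.

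Other cell types of the spleen were lower too. Of 17 macrophage genes 16 fell, 17 adjusted over the list alone (median -2.0, camera adjusted p = 5.6e-07, and adjusted p = 0.409 with an estimated correlation), with the receptor Csf1r (-3.24, SE 0.16) and Marco (-2.81). Of 17 T cell genes 11 fell and 1 rose (median -3.20, camera adjusted p = 1.8e-06, and adjusted p = 0.291 with an estimated correlation), Trat1 and Bcl11b being at least 7.24-fold and 22.8-fold lower. Of 10 NK and cytotoxic genes 8 fell (median -2.56, camera adjusted p = 1.2e-05, and adjusted p = 0.204 with an estimated correlation), Nkg7 by 4.54. Of 18 erythroid genes 15 fell, 16 adjusted over the list alone (median -2.74, camera adjusted p = 1.2e-05), and all 9 megakaryocyte genes fell (median -2.69, camera adjusted p = 0.00036), both with adjusted p = 0.602 with an estimated correlation. Late neutrophil genes fell (3 of 11, median -1.47, camera adjusted p = 0.0429, and adjusted p = 0.626 with an estimated correlation). The cortical thymocyte, Hoxc and Hoxd, and tumour suppressor lists differed in sign between median, mean and test and were not called.

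Without wild-type spleen replicates 1, 2 and 3 the count was 2440, 2334 and 2616 against 4208, and 2352 with a term for sex (Y genes on 1 of 4 B-ALL and 3 of 3 wild-type arrays). Scaling to the median gave 2707 rises and 1832 falls.

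Which genes changed in all 3 leukaemias was counted over 9542 genes tested in each. There were 136 genes higher in all 3, with 29.7 expected if the calls were independent, and 145 lower, with 19.5 expected; the expectation takes no account of the shared animals. The 136 included Hoxa5, Hoxa7, Hoxa9 and Hoxa10. Bahcc1 (2.29, 2.57 and 5.43 in AML, T-ALL and B-ALL), the kinase Camk2b (1.97, 2.24 and 2.06), the relaxin family gene Insl6 (3.73, 1.77 and 3.40) and the proteasome gene Psmb1 (3.61, 1.54 and 2.10) were also among them.

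Whether the change from control tissue differs between leukaemias was tested on 32 Hox, Meis and Pbx family genes, adjusted over these genes alone. The AML effect exceeded the T-ALL effect for 9 genes, with Meis1 (3.40, SE 0.96, adjusted p = 0.00773), Meis2 (3.05, SE 0.40, adjusted p = 1.1e-06) and Hoxa5 (2.99, SE 0.46, adjusted p = 6.6e-06) the furthest apart, and Hoxa7 (1.06) closer. Meis2 was mostly at background in marrow, so its difference rests on the fall in T-ALL. AML and B-ALL differed for 3 genes, Hoxa5 (2.03, SE 0.49, adjusted p = 0.0042), Meis2 (2.5) and Pknox1 (-0.97). A second Pknox1 probe rose less in B-ALL (0.46 against 0.88) and changed by 0.06 in AML and -0.16 in T-ALL. T-ALL and B-ALL differed for 6, with Hoxa7 (-1.84, SE 0.38, adjusted p = 0.00061) having the smaller rise in T-ALL. Of the other 5, Hoxc6, Hoxd8 and Pbx3 were at background on most arrays of at least 1 group, so their sizes are not exact. The Hoxa5 differences lay mostly in the controls: AML, T-ALL and B-ALL stood at 11.34, 10.98 and 11.36, and wild-type marrow, thymus and spleen at 5.79, 8.41 and 7.83. The marrow level was close to background, so the Hoxa5 differences of AML from T-ALL and B-ALL are not exact in size. For Hoxa7 the levels were 11.78, 10.97 and 11.64 against 7.23, 7.48 and 6.31. Hoxa5 no longer differed between AML and B-ALL without background correction or with the authors' values.

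**Figure D1:**
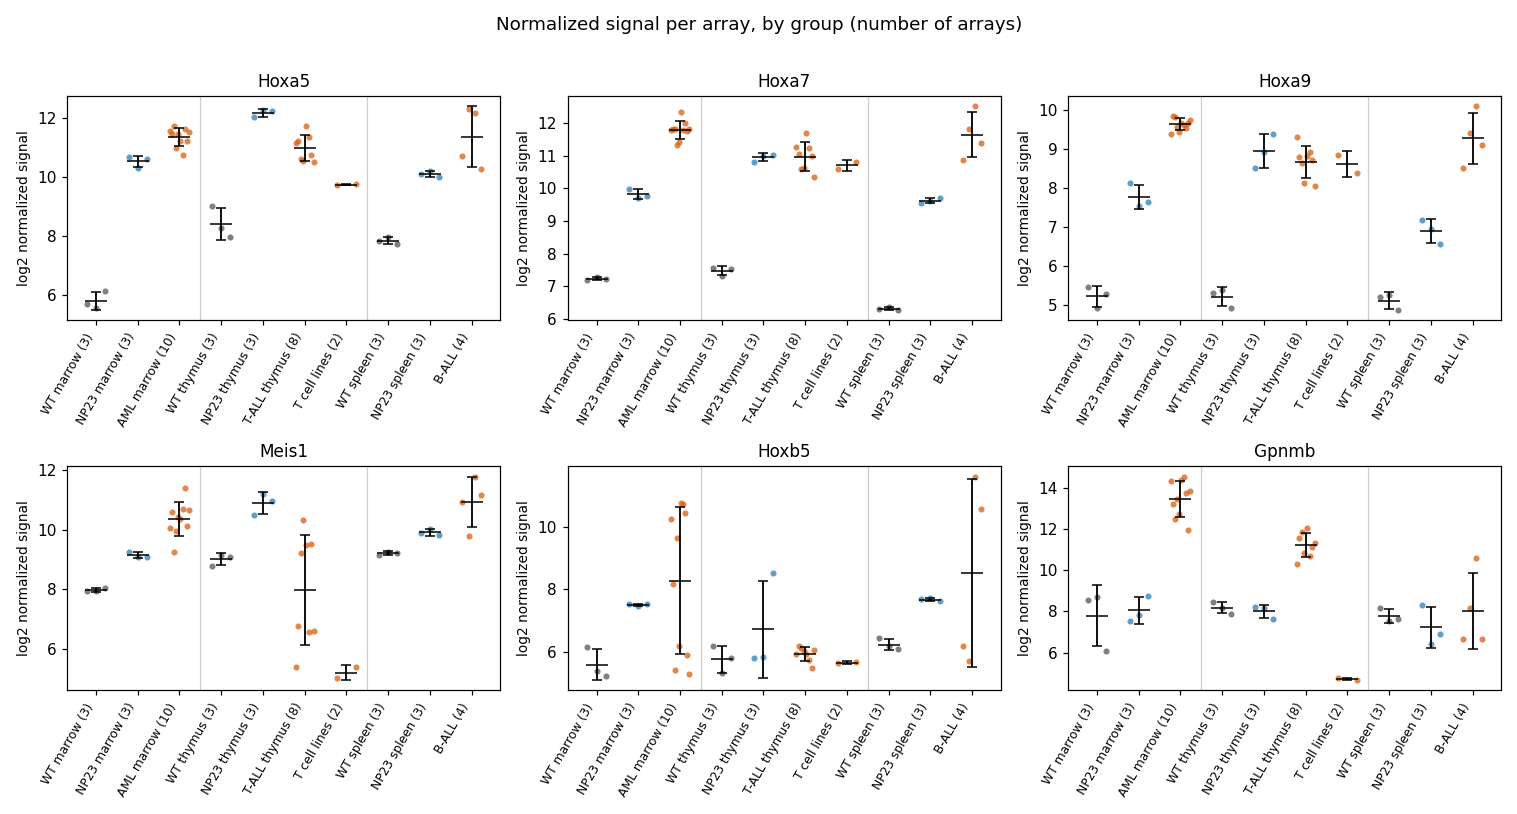
Normalized log2 signal of Hoxa5, Hoxa7, Hoxa9, Meis1, Hoxb5 and Gpnmb on each array (points) of 10 groups, with the group mean and SD as black bars. Hoxa7 lay at 7.23 in wild-type marrow, 9.82 in healthy NP23 marrow and 11.78 in AML, while Meis1 in T-ALL was spread (SD 1.84).

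The fourth comparison asked what the transgene changes in marrow before disease, with healthy NP23 and wild-type marrow at n = 3 each. Hoxa5 rose by 4.74 log2 (SE 0.20, adjusted p = 0.0003) to 10.53 (SD 0.19). Its wild-type level was close to background, so this size is not exact. Hoxa7 rose by 2.58 (SE 0.14, adjusted p = 0.0012), Bahcc1 by 2.47 (SE 0.16, adjusted p = 0.002), and Hoxa9 was at least 4.81-fold higher (adjusted p = 0.01). Nkx2-3 (1.87, SE 0.16), Capsl (1.75, SE 0.17) and Insl6 (1.58, SE 0.17) completed the 7 calls among 9472 genes tested with limma at a Benjamini-Hochberg adjusted p under 0.05. All 7 rose at least 2-fold, none fell, and 517 genes had an unadjusted p under 0.05.

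Meis1 (1.17, SE 0.14, adjusted p = 0.052) and Hoxb5 (1.92, SE 0.25, adjusted p = 0.073) were not called, nor were Pbx3 (0.06), Phf23 (0.13) or Nup98 (-0.09), and Hoxa10 and Hoxb8 were not tested. Of 5 Hoxa genes 3 rose, 4 adjusted over the list alone (median 2.54, camera adjusted p = 4.1e-15), and of 4 Hoxb genes none rose, 3 adjusted over the list alone (median 1.21, camera adjusted p = 2.6e-06). The precursor B list rose with no gene called, 2 adjusted over the list alone (median 0.44, camera adjusted p = 2.5e-05), and these 3 lists had an adjusted p = 0.0792 with an estimated correlation. The mature B list (median 0.34, camera adjusted p = 0.0031, and adjusted p = 0.58 with an estimated correlation) and the erythroid list (median 0.22, camera adjusted p = 0.00269, and adjusted p = 0.776 with an estimated correlation) rose with no gene called. The cortical thymocyte list rose too, with none of 9 genes called (median 0.25, camera adjusted p = 0.00695, and adjusted p = 0.413 with an estimated correlation). The T cell list fell (median -0.26, adjusted p = 0.413 with an estimated correlation), as did the NK list (median -0.46, 4 of 8 genes adjusted over the list alone, adjusted p = 0.272 with an estimated correlation) and the interferon list (median -0.38, adjusted p = 0.846 with an estimated correlation), each at a camera adjusted p = 0.00145. The interferon fall rests largely on wild-type replicate 3, with a mean log2 signal of 9.14 over this list. Wild-type replicates 1 and 2 had 8.07 and 8.25, and NP23 marrow 8.33, 7.93 and 8.02. The macrophage, megakaryocyte and cell cycle lists differed in sign between median, mean and test and were not called.

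The count of 7 fell to 3, 3 and 4 without NP23 marrow replicates 1, 2 and 3 and to 3 without wild-type marrow replicate 2 or 3, and was 38 with array weights. The 2 dimmest arrays by the 75th percentile of signal were wild-type replicate 1 (233) and NP23 replicate 2 (209). Without them, a choice made after seeing the data, the count was 2.

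The fifth comparison asked the same of thymus, with n = 3 each. Hoxa5 rose by 3.77 log2 (SE 0.26, adjusted p = 0.0031) to 12.17 (SD 0.14), Hoxa9 by 3.72 (SE 0.24, adjusted p = 0.003) and Hoxa7 by 3.47 (SE 0.13, adjusted p = 0.00029). The Hoxa9 size is not exact, as wild-type thymus was close to background. Meis1 rose by 1.88 (SE 0.21, adjusted p = 0.025), and Bahcc1 by 3.17 (SE 0.15, adjusted p = 0.00078). Myl10, a myosin light chain gene, rose by 4.01 (SE 0.31, adjusted p = 0.0038), and Ccl5, a chemokine of cytotoxic T cells, fell by 1.16 (SE 0.16, adjusted p = 0.049). Of 10753 genes tested with limma, 31 were called at a Benjamini-Hochberg adjusted p under 0.05, 19 higher and 12 lower, 18 and 11 of them at least 2-fold, and 1088 had an unadjusted p under 0.05.

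Further rises were the glucose transporter family gene Slc5a9 (2.96, SE 0.20), Insl6 (2.76), the lipocalin Lcn4 (2.41), Hoxa2 (1.58) and the metalloprotease gene Adamts18, at least 3.68-fold higher. Further falls were the NK receptor Klra7 (-1.72), the linker histone H1f10 (-1.44), Podxl2 (-1.32), Smoc1 (-1.31) and Ampd1 (-1.21), with Adam12 at least 2.04-fold and Art1 at least 1.70-fold lower. Hoxa10, not well above background in wild-type thymus (adjusted p = 0.15), Hoxb5 (0.96, adjusted p = 0.72), Pbx3 (0.28), Nup98 (0.08) and Phf23 (-0.39) were not called. Of 8 Hoxa genes 4 rose, 7 adjusted over the list alone (median 1.49, camera adjusted p = 1.6e-14, and 0.0299 with an estimated correlation). The T cell list fell (median -0.40, camera adjusted p = 1.7e-06) with none of 17 genes called and 2 adjusted over the list alone, as did the cortical thymocyte list (median -0.44, camera adjusted p = 0.00439); the Notch target (median 0.36, camera adjusted p = 0.00439), megakaryocyte (median 0.60, camera adjusted p = 0.0212) and thymic epithelium lists (median 0.39, camera adjusted p = 0.0243) rose. All 5 had an adjusted p = 0.598 with an estimated correlation. The Myc target list rose (median 0.21, camera adjusted p = 0.0477, and adjusted p = 0.709 with an estimated correlation), and the stem and plasma cell lists differed in sign between median, mean and test.

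Without NP23 thymus replicates 1, 2 and 3 the count of 31 became 15, 9 and 59, without wild-type replicates 1, 2 and 3 it became 8, 9 and 11, and with a term for sex, added after seeing the data, 7; only 1 NP23 thymus had the Y genes of the 3 wild-type ones. The split of 19 rises and 12 falls was 19 and 7 with median scaling and 12 and 4 with the authors' values.

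The sixth comparison asked the same of spleen, with n = 3 each. Hoxa7 rose by 3.30 log2 (SE 0.10, adjusted p = 2.5e-05), from 6.31 (SD 0.04) to 9.62 (SD 0.08), Hoxa5 by 2.27 (SE 0.11, adjusted p = 0.0003) and Bahcc1 by 2.68 (SE 0.12, adjusted p = 0.0003). Gata1, the main regulator of red cell and megakaryocyte genes, rose by 1.81 (SE 0.22, adjusted p = 0.015). Il21, a cytokine of follicular helper T cells, was at least 2.75-fold lower (adjusted p = 0.0003). Of 10388 genes tested with limma, 448 were called at a Benjamini-Hochberg adjusted p under 0.05, 307 higher and 141 lower, 123 and 35 of them at least 2-fold.

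Hoxa9 was at least 2.97-fold higher, and of 6 Hoxa genes 4 rose, 5 adjusted over the list alone (median 1.55, camera adjusted p = 8.3e-09, and adjusted p = 0.121 with an estimated correlation). Of 6 Hoxb genes 4 rose, 4 adjusted over the list alone (median 0.94, camera adjusted p = 6.5e-06, and adjusted p = 0.211 with an estimated correlation): Hoxb7 (1.52, SE 0.14), Hoxb5 (1.44, SE 0.12), Hoxb2 (0.95) and Hoxb6, at least 1.30-fold higher. Meis1 rose by 0.69 (SE 0.10, adjusted p = 0.027), and Pbx3 (0.26), Nup98 (0.07) and Phf23 (-0.19) were not called. Red cell genes rose: the sterol transporter Abcg4 (2.31), Slc38a5 (2.24), Tspo2 (2.03), Gfi1b (2.03, SE 0.44) and Ermap (1.95, SE 0.39). Of 18 erythroid genes 3 rose, 15 adjusted over the list alone (median 1.47, camera adjusted p = 1.5e-09, and adjusted p = 0.334 with an estimated correlation). Of 21 cell cycle genes 7 rose, 18 adjusted over the list alone (median 0.91, camera adjusted p = 5.4e-13, and adjusted p = 0.334 with an estimated correlation), with Mcm2 (1.14, SE 0.22) and Plk1 (0.92, SE 0.17). Of 9 megakaryocyte genes 2 rose, 8 adjusted over the list alone (median 1.13, camera adjusted p = 1.4e-07, and adjusted p = 0.334 with an estimated correlation), Vwf (1.55) and Itga2b (1.23), and of 12 late neutrophil genes 1 rose, 7 adjusted over the list alone (median 0.78, camera adjusted p = 4.2e-07, and adjusted p = 0.334 with an estimated correlation), Retnlg (1.47).

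T cell genes fell, 1 of 17 and 11 adjusted over the list alone (median -0.60, camera adjusted p = 1.5e-07, and adjusted p = 0.334 with an estimated correlation), Tcf7 by 0.76. Of 10 NK genes 2 fell, 7 adjusted over the list alone (median -0.57, camera adjusted p = 6.8e-05), Klrb1c by 1.24, and of 10 plasma cell genes 3 fell, 7 adjusted over the list alone (median -0.71, camera adjusted p = 9.7e-05), Derl3 by 0.99 and Mzb1 by 0.54. The NK and plasma cell lists also had an adjusted p = 0.334 with an estimated correlation. The mature B list fell with no gene called (median -0.19, camera adjusted p = 0.019, and adjusted p = 0.723 with an estimated correlation). The macrophage list, of 17 genes, did not move (median -0.03, camera adjusted p = 0.839). The chromatin and tumour suppressor lists differed in sign between median, mean and test and were not called.

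Against 448, the count was 45, 64 and 20 without NP23 spleen replicates 1, 2 and 3, 63 and 42 without wild-type replicates 1 and 2, 106 with all groups in 1 fit and 17 with a term for sex, which rests the comparison on the only NP23 spleen with Y genes. Scaling to the median gave 800 rises and 102 falls in place of 307 and 141.

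**Figure D2:**
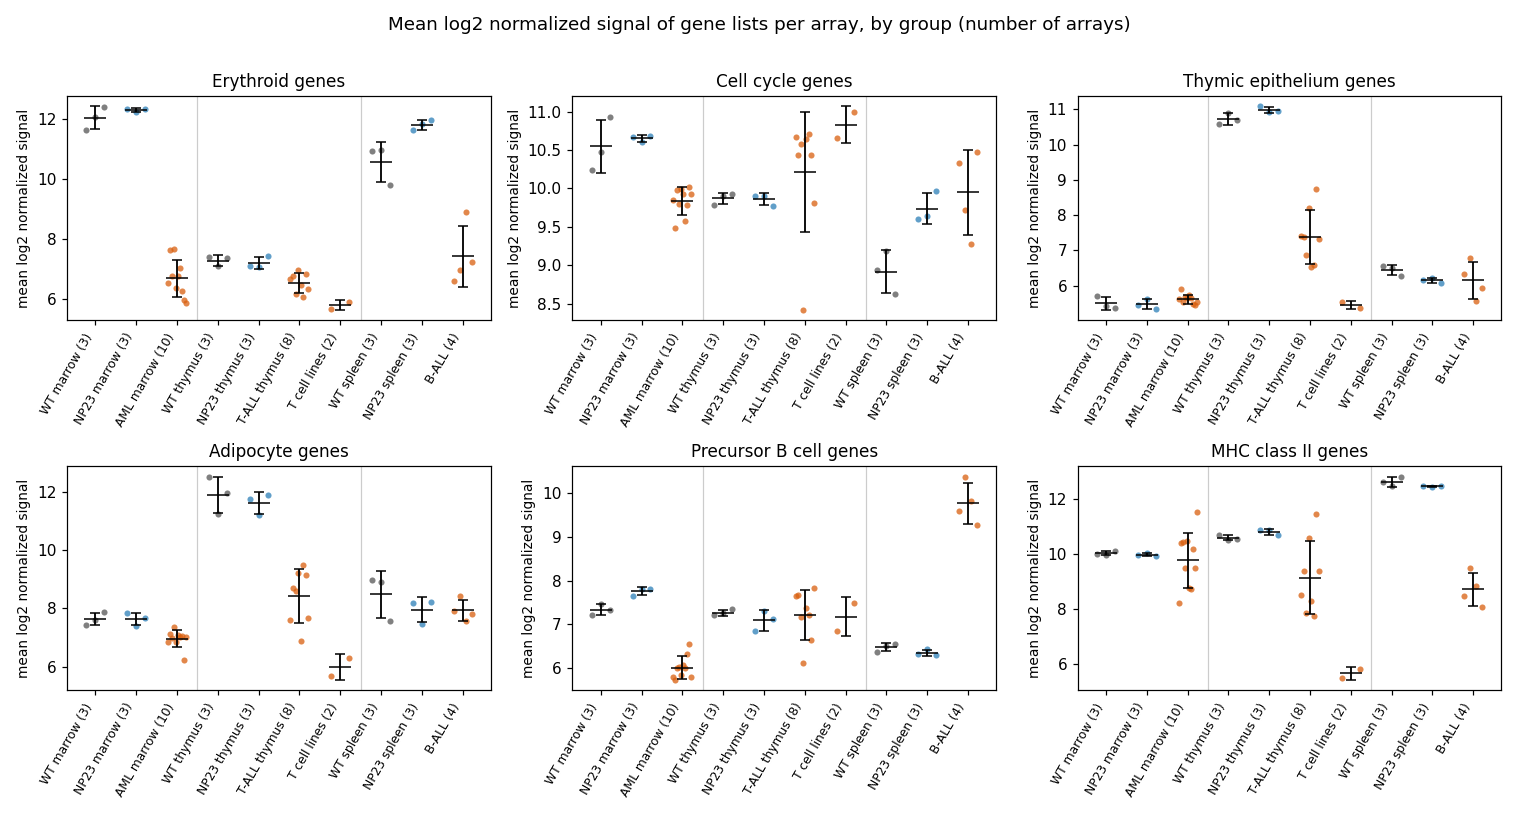
Mean log2 signal of the erythroid, cell cycle, thymic epithelium, adipocyte, precursor B and MHC class II lists on each array (points), by group. The NP23 spleens stood above the wild-type spleens for cell cycle and erythroid genes, and T-ALL thymus stood below both healthy thymus groups for epithelium and adipocyte genes.

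Across healthy NP23 tissues, 4 of 8866 genes tested in all 3 were higher in each and none was lower, thymus and spleen sharing their animals: Hoxa5 (4.74 in marrow, 3.77 in thymus, 2.27 in spleen), Hoxa7 (2.58, 3.47, 3.30), Hoxa9 (at least 4.81-fold, 3.72 log2 and at least 2.97-fold) and Bahcc1 (2.47, 3.17, 2.68). Wild-type Hoxa9 was close to background in thymus too (5.33, 5.39 and 4.94), so its sizes cannot be compared between tissues. Hoxa5 was close to background in wild-type marrow. Whether the transgene effect differs between tissues was tested directly. Between marrow and thymus 2 of 11387 genes differed, Slc5a9 (-2.96, SE 0.28, adjusted p = 0.0031) and Cfap20dc (-2.0, SE 0.25, adjusted p = 0.032), both with the lower effect in marrow, and 975 had an unadjusted p under 0.05. Neither gene was well above background in marrow. In those 12 arrays no list member was called, and the lists for precursor B genes (median 0.63, camera adjusted p = 0.00744), cortical thymocyte genes (median 0.69, camera adjusted p = 9.5e-05), mature B genes (0.66, 0.0176) and erythroid genes (0.38, 0.0395) were higher. The interferon (-0.41, 0.00744), Hoxa (-0.55, 0.0409), megakaryocyte (-0.69, 0.0409) and Notch lists (-0.39, 0.0432) were lower, all 8 with adjusted p = 0.449 to 0.7 with an estimated correlation. The interferon result includes wild-type marrow replicate 3, which was high for this list.

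Between thymus and spleen 323 of 11508 genes differed, 155 with the higher effect in thymus and 168 in spleen. The count fell without the animal block or with all groups in 1 fit. It rose without background correction or with the authors' values, as given under processing. Myl10 (3.72, SE 0.35) and Slc5a9 (2.98, SE 0.20), neither well above background in spleen, had the higher effect in thymus. Fn3k, which encodes a kinase of glycated proteins, had the higher effect in spleen (-2.80, SE 0.45), as did Abcg4 (-2.48, SE 0.51) and Ermap (-1.98, SE 0.42), which were mostly at background in thymus. Cell cycle (median -0.92, camera adjusted p = 3.0e-12) and erythroid genes (median -1.41, camera adjusted p = 2.4e-10), 4 called genes in each, had the higher effect in spleen, both with adjusted p = 0.29 with an estimated correlation. The late neutrophil (-1.09, camera adjusted p = 0.00204) and megakaryocyte lists (-0.77, 0.00435) did so too. Hoxa genes (0.37, camera adjusted p = 0.00317, and adjusted p = 0.184 with an estimated correlation), plasma cell (0.63, 0.00435), epithelium (0.44, 0.00435), MHC class II (0.31, 0.00448) and NK genes (0.47, 0.043) had the higher effect in thymus; apart from the Hoxa list these had adjusted p = 0.29 to 0.535 with an estimated correlation. Between marrow and thymus the count reached 20 without NP23 thymus replicate 3, 6 without replicate 1 and 1 without replicate 2, NP23 marrow replicates 1, 2 or 3, wild-type marrow replicates 2 or 3 or wild-type thymus replicate 3, and it was 69 with array weights. Between thymus and spleen it was 180, 172 and 520 without NP23 thymus replicates 1, 2 and 3, 110, 191 and 132 without wild-type thymus replicates 1, 2 and 3, 129, 184 and 66 without NP23 spleen replicates 1, 2 and 3, and 213 and 206 without wild-type spleen replicates 1 and 3; median scaling split it into 123 and 319.

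The 2 T cell lines were compared with wild-type thymus (n = 3), asking what the tumour cells express without tissue around them. Hoxa9 rose by 3.39 log2 (SE 0.24, adjusted p = 0.00042), Hoxa7 by 3.22 (SE 0.18, adjusted p = 0.0002) and Hoxa5 by 1.32 (SE 0.33, adjusted p = 0.026). The Hoxa9 size is not exact, as wild-type thymus was close to background. Meis1 was at least 9.63-fold lower (adjusted p = 0.0002). Myc rose by 2.81 (SE 0.20, adjusted p = 0.00044) and the Notch target Hes1 by 3.11 (SE 0.40, adjusted p = 0.0033). Of 10978 genes tested with limma, 4593 were called at a Benjamini-Hochberg adjusted p under 0.05, 2357 higher and 2236 lower, and 1193 rose and 1770 fell at least 2-fold.

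The largest rises were Spsb4 (at least 20.5-fold), the homeobox gene Dlx1 (at least 19.0-fold), Sall3 (at least 13.2-fold), Ncald (4.18) and the amino acid enzyme Bcat1 (3.39). Notch regulator Dtx1 (3.34), Lef1 (2.20), Bmi1 (2.14), Runx1 (2.0), Gata3 (1.89), Nup98 (1.60), Pbx3 (1.40) and Ezh2 (1.37) rose, and Phf23 (0.50) and Hoxb5 (-0.11) stayed close to thymus. Of 6 Hoxa genes 4 rose (median 1.07, camera adjusted p = 0.0526, not called). Cell cycle (12 of 21 rose, median 0.75) and Myc target genes (9 of 15 rose, Myc itself on the list, median 1.17) were called at a camera adjusted p = 0.0003 each, with adjusted p = 0.376 and 0.5 with an estimated correlation. All 9 epithelium and all 9 adipocyte genes fell (medians -5.77 and -6.74, camera adjusted p = 1.5e-08 and 9.1e-06, each with adjusted p = 0.376 with an estimated correlation), with Krt18 at least 36.3-fold and Lpl at least 255-fold lower. So did 15 of 17 macrophage genes (median -4.05, camera adjusted p = 3.4e-09), C1qb at least 32.9-fold, 9 of 10 MHC class II genes (median -4.37, camera adjusted p = 5.2e-07), 9 of 13 stroma genes (median -3.10, camera adjusted p = 0.00043) and 9 of 16 interferon genes (median -1.78, camera adjusted p = 0.0003). These 4 lists had the same adjusted p = 0.376 with an estimated correlation. Cortical thymocyte genes (8 of 13 fell, median -1.47, camera adjusted p = 0.0209, and adjusted p = 0.393 with an estimated correlation) included Cd4 (-3.47), Rag1 (-2.13) and Satb1 (-2.06), and late neutrophil genes fell (8 of 10, median -1.83, camera adjusted p = 0.00014, and adjusted p = 0.443 with an estimated correlation). T cell genes did not move as a list (median -0.09), and the Meis and Pbx and the stem lists differed in sign between median, mean and test.

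Each line carries the number of an animal that also gave a T-ALL sample, and neither had both Y genes detected against 3 of 3 thymuses. The count was 2718 and 2797 without wild-type thymus replicates 1 and 3, against 4593, and median scaling gave 3448 rises and 1897 falls in place of 2357 and 2236, with a median over all genes of 0.39 instead of 0.14.

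The last comparisons asked what separates leukaemia from healthy tissue of the same genotype. AML (n = 10) against NP23 marrow (n = 3) still had higher Hoxa7 (1.96 log2, SE 0.17, adjusted p = 9.9e-07), Hoxa9 (1.86, SE 0.14, adjusted p = 1.9e-07), Hoxa10 (1.42, adjusted p = 0.0022), Meis1 (1.2, SE 0.31, adjusted p = 0.0086) and Hoxa5 (0.82, SE 0.19, adjusted p = 0.0044). Gpnmb (5.42, SE 0.49), Slc4a8 (4.83), Dpep2 (4.37), Nkx2-3 (3.83, SE 0.68), the T cell costimulatory gene Cd28 (3.18), Psmb1 (3.56, SE 0.21) and the cell cycle inhibitor Cdkn1a (2.30) rose. Trim10 (-8.63), Alas2 (-8.59) and Vpreb3 (-7.24) fell. Of 10464 genes tested with limma, 3425 were called at a Benjamini-Hochberg adjusted p under 0.05, 2046 higher and 1379 lower, and 679 rose and 816 fell at least 2-fold.

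Of 9 Hoxa genes 6 rose (median 0.92, camera adjusted p = 0.00889, and adjusted p = 0.212 with an estimated correlation). Of 18 erythroid genes 17 fell (median -5.68, camera adjusted p = 3.0e-23) and of 12 mature B genes 10 (median -3.12, camera adjusted p = 1.9e-10), both at 0.0021 with an estimated correlation. Cell cycle genes (13 of 21 fell, 16 adjusted over the list alone, median -0.72, camera adjusted p = 1.1e-06) and precursor B genes (6 of 9 fell and 1 rose, median -1.45, camera adjusted p = 0.00344) had an adjusted p = 0.212 with an estimated correlation. Megakaryocyte genes fell as well (8 of 9, median -2.07, camera adjusted p = 0.00028, and adjusted p = 0.377 with an estimated correlation), as did late neutrophil genes (3 of 15, median -1.71, camera adjusted p = 0.00695, and adjusted p = 0.776 with an estimated correlation). Cortical thymocyte (median -0.55, camera adjusted p = 0.0329) and Notch target genes (median -0.54, camera adjusted p = 0.0208) were lower, each with adjusted p = 0.346 with an estimated correlation. Phf23 rose by 0.77 (adjusted p = 0.038), and Hoxb5 (0.77, adjusted p = 0.68), Nup98 (0.31) and Pbx3 (0.28) were not called. The Meis and Pbx, primary granule, plasma cell and adipocyte lists differed in sign between median, mean and test. Median scaling gave 4197 rises and 819 falls in place of 2046 and 1379, with a median over all genes of 0.41 instead of 0.09.

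In T-ALL (n = 8) against NP23 thymus (n = 3) no Hoxa gene rose. Hoxa7 (0.02, SE 0.26, adjusted p = 0.96), Hoxa9 (-0.27, adjusted p = 0.53) and Hoxa10 (0.08, adjusted p = 0.91) did not change, Hoxa5 fell by 1.2 (SE 0.26, adjusted p = 0.01), Hoxa4 by 1.12 (adjusted p = 0.0034) and Meis2 fell by 2.85 (SE 0.33, adjusted p = 0.00017). Meis1 (-2.90, SE 0.98, adjusted p = 0.07), Hoxb5 (-0.79, adjusted p = 0.28), Nup98 (0.56) and Phf23 (0.67) were not called, and Pbx3 rose by 1.13 (adjusted p = 0.039). Arg1, at least 20-fold higher (adjusted p = 0.0033), Gpnmb (3.21, SE 0.34), the low-affinity IgG receptor Fcgr4 (2.49), the myeloid receptor Trem2 (1.99), Cd68 (1.36), Olig3 (1.90) and Myc (1.38, adjusted p = 0.0065) rose. Of 11018 genes tested with limma, 1605 were called at a Benjamini-Hochberg adjusted p under 0.05, 578 higher and 1027 lower, and 115 rose and 811 fell at least 2-fold.

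Of 9 Hoxa genes 3 fell (median -0.27, camera adjusted p = 0.14, not called). Of 9 epithelium genes 8 fell (median -4.38, camera adjusted p = 2.4e-09) and of 9 adipocyte genes 7 (median -3.57, camera adjusted p = 8.3e-08), 9 of each adjusted over the list alone and both with adjusted p = 0.327 with an estimated correlation. Krt18 (-5.37, SE 0.50), Ccl25 (-5.25), Trp63 (-4.50) and Lep (-3.64) were examples, and Tbata fell by 8.40 (SE 1.05). The Tbata size rests on dim T-ALL signals and is not exact. MHC class II genes (0 of 10 called, median -1.95, camera adjusted p = 0.0208) and interferon genes (median -0.50, camera adjusted p = 0.042) fell and Myc targets rose (2 of 15 with Myc itself on the list, 6 adjusted over the list alone, median 0.58, camera adjusted p = 0.015), all 3 with adjusted p = 0.906 with an estimated correlation. The Hoxc and Hoxd, Meis and Pbx, stem, T cell, plasma cell, p53 and tumour suppressor lists differed in sign between median, mean and test. The count was 583, 708 and 505 without NP23 thymus replicates 1, 2 and 3, against 1605, 770 with a term for sex and 3778 with array weights. No T-ALL array met the rule of the sex term (both Y genes at a detection p under 0.01). That term therefore only set aside NP23 thymus replicate 3 and left 2 NP23 arrays.

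**Figure D3:**
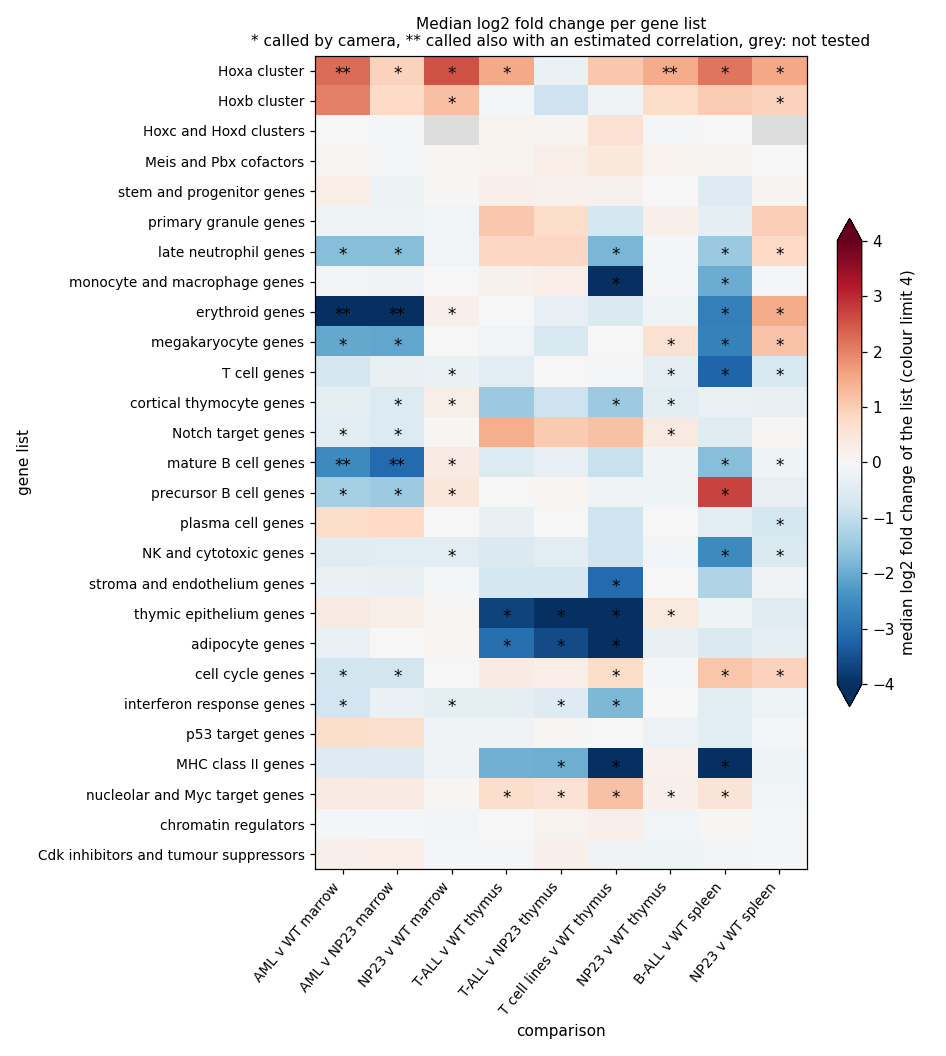
Median log2 change of each list in 9 comparisons, with 1 star for a camera call, 2 where it held with an estimated correlation, and grey where not tested. The Hoxa list is positive in all comparisons but T-ALL against healthy NP23 thymus (-0.27).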

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

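The tests of lymphocytes, of fat on some thymuses and of dilution below were written only after the result was seen. A sample was picked out when it lay far from the rest of its group of 4 to 10 arrays by Dixon's test at 95%, which chance does in about 1 in 20 groups. Of 237 such checks 28 were met, with 11.85 expected.

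In AML, replicate 9 stood apart for the Notch target score (7.05), the adipocyte score (6.23) and the Notch target Nrarp (6.19), and replicate 4 for Vpreb3 (5.69) and Gp5 (8.08). Single AML arrays stood apart for Nkx2-3 (8.50, replicate 10), Slc4a8 (13.6, replicate 6), Blk (6.23, replicate 3), Prss34 (8.13, replicate 8) and Spic (7.25, replicate 2). T-ALL replicate 4 stood apart for the cortical thymocyte (7.02), cell cycle (8.42) and chromatin regulator scores (8.61), Arg1 (13.1), Hoxd8 (6.12) and the Y-linked Eif2s3y (7.89) and Kdm5d (5.58). T-ALL replicate 7 did so for the epithelial genes Krt18 (8.49), Ccl25 (11.8) and Tbata (10.6), and replicate 8 for Bahcc1 (7.62) and Hoxb8 (5.03, not above background). In B-ALL, replicate 3, the marrow sample, stood apart for the megakaryocyte score (8.0), Bahcc1 (11.9) and Marco (5.13, not above background), replicate 1 for the macrophage score (9.24) and Insl6 (13.4), and replicate 2 for Rag1 (11.6). All values are log2 signals.

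Effects that differed between groups by a direct test were picked out next. The AML effect exceeded the T-ALL effect for Hoxa2 (1.60), Hoxa4 (1.14), Hoxa5 (2.99), Hoxa7 (1.06), Hoxa9 (0.94), Hoxc6 (1.55), Hoxd8 (1.02), Meis1 (3.40) and Meis2 (3.05). Hoxa4 and Hoxa9 were at background in wild-type marrow and Hoxa5 close to it, so the sizes of their differences are not exact. Hoxc6, Hoxd8 and Meis2 were at background on nearly all marrow arrays. AML and B-ALL differed for Hoxa5 (2.03), Meis2 (2.5) and Pknox1 (-0.97), and T-ALL and B-ALL for Hoxa4 (-1.12), Hoxa7 (-1.84), Hoxc6 (-2.14), Hoxd8 (-1.63), Pbx3 (1.66) and Pknox1 (-0.93). A second Pknox1 probe rose less in B-ALL (0.46 against 0.88). The sizes for Hoxc6, Hoxd8 and Pbx3 are not exact: Hoxc6 was detected on 0 of 8 T-ALL, 1 of 4 B-ALL and 0 of 3 wild-type spleen arrays, Hoxd8 on 1, 2 and 0, and Pbx3 on 0 of 4 B-ALL arrays. These differences include the controls: Hoxa5 stood at 11.34 in AML and 11.36 in B-ALL, and at 5.79 and 7.83 in wild-type marrow and spleen. The NP23 effect differed for 2 genes between marrow and thymus and for 323 between thymus and spleen.

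Samples outside the main comparisons had Hox genes above the highest wild-type arrays, which stood at 9.0 for Hoxa5, 7.57 for Hoxa7 and 5.46 for Hoxa9. In that order the values were 12.04, 11.49 and 9.65 in the AML lymph node replicate 1, 11.06, 10.93 and 8.62 in replicate 2, and 11.42, 11.37 and 10.06 in the T-ALL spleen. They were 10.64, 10.89 and 8.96 in the T-ALL lymph node, 12.93, 12.02 and 10.31 in the sample with conflicting labels and 9.45, 8.39 and 6.30 in the spleen labelled erythroid.

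Relabelling the arrays gave as many called genes as the real grouping in 1 of 100 splits for AML against wild-type marrow (3282, highest other 16), T-ALL against wild-type thymus (2070, highest other 14), AML against NP23 marrow (3425, highest other 6) and T-ALL against NP23 thymus (1605, highest other 11), the real one included, and in 1 of 35 for B-ALL (4208, highest other 346). With 3 arrays against 3 the 10 splits are too few for a share under 0.05. There the real counts and highest others were 7 and 0 for NP23 marrow, 31 and 3 for thymus, 448 and 0 for spleen, and 323 and 4 for the thymus and spleen difference, 1 split of 10 each. For the marrow and thymus difference 16 of 100 splits gave 2 genes or more, up to 91, so chance was not excluded.

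The rise of erythroid and cell cycle genes in healthy NP23 spleen was weighed first. A loss of lymphocytes would raise all other cell types alike, but the erythroid change exceeded the macrophage change by 1.28 (SE 0.43, changes 1.24 and -0.04). Macrophages were the only reference, and a loss of them could hide such a rise. The megakaryocyte (median 1.13) and late neutrophil lists (0.78) rose, the stroma list (-0.14) did not. T cell (-0.60), NK (-0.57) and plasma cell lists (-0.71) fell. Loss of lymphocytes was therefore not excluded. Sex is open: the only NP23 spleen with both Y genes detected had an erythroid score 0.86 above the highest wild-type spleen, but 1 array cannot tell sex and transgene apart. Blood left in the spleen was not tested and stays open. A transgene effect, the difference the design names, was not tested against these.

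For the fall of epithelial and fat cell genes in T-ALL thymus, fat on only some of the healthy thymuses was not the reason for the adipocyte list, because the lowest of the 6 healthy arrays lay 1.71 log2 above the highest T-ALL array for the adipocyte score (SD of the healthy arrays 0.488); fat trimmed from all tumours and left on all healthy thymuses stays open. The brown fat gene Cidea, outside that list test, stood at 6.68 in NP23 thymus replicate 2, within the T-ALL range (up to 9.24), so brown fat on some thymuses only was not excluded. Dilution by tumour cells would lower all other cell types alike, but the epithelium change lay at -3.39 (SE 0.34) relative to the macrophage change of 0.04. Arg1 and Gpnmb rose in T-ALL, however, as did Cd68 alone of 17 macrophage genes. A gain of macrophages in the tumours could offset dilution, so dilution was not excluded. Quantile normalization was not the reason, as the list median was -3.47 with median scaling. It was -2.72 with the authors' values, whose normalization method is not known. Dilution, loss of epithelium within the tumours and sampling of tumour regions free of it stay open.

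The fall of cell cycle genes in AML marrow was weighed last. A loss of dividing red cell precursors, a possible cause, was predicted to give a positive correlation across the AML arrays. Over the 10 AML arrays the cell cycle and erythroid scores had Spearman rho -0.59 (permutation p 0.0803) and Pearson r -0.67 (permutation p 0.0358), and r -0.51 without the 2 farthest arrays. The rank correlation planned for this did not pass. The erythroid score was 5.86 to 7.66 in AML and 11.6 to 12.4 in wild-type marrow. Spread among AML arrays therefore says little about a loss relative to wild type, and the explanations cannot be told apart. Quantile normalization alone was not the reason, as the list median was -0.51 with median scaling (camera adjusted p = 7.3e-06). It was -0.56 without background correction and -0.57 with the authors' values. Those settings cannot test this, as the first was also quantile normalized and the method behind the authors' values is not known. The list call itself was lost with an estimated correlation (adjusted p = 0.355). A slower cycle of the leukaemic cells stays open.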

How the results depend on the processing

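No test in this part other than the sex terms, the animal block and other settings for the Hox differences, the removal of genes on X and Y, median scaling for lists and the removal of the 2 dimmest marrow arrays was chosen after the result was seen; the other settings were fixed before the data were examined. No paired analysis was possible because the 2 groups of each comparison come from different animals, and replicate numbers follow the order of deposit; the thymus and spleen difference, which shares animals, had the animal as a block. The Hox differences also share animals; with the animal as a block (correlation 0.279), added after the result was seen, they numbered 9, 3 and 8 against 9, 3 and 6. A slide effect was not run because the files give no slide, and array weights did not fully converge in 3 fits. Of named gene results, 12471 kept their call under another setting, 551 became weaker, 343 stronger, and 1 that was called in either fit turned direction. Of list results 1060 kept their call, 99 became weaker and 21 stronger, and none called in either fit turned direction. A result called in neither fit counted as kept even where its sign turned. Counts of called genes stayed within 1.5 times in 110 and moved in 32, as follows; the cause was not tested. With array weights the counts were 5704 for AML (against 3282) and 4403 for T-ALL (2070) against wild type, 38 for NP23 marrow (7), 3778 for T-ALL against NP23 thymus (1605) and 69 for the marrow and thymus difference (2). With all groups in 1 fit they were 3289 and 2705 for the T-ALL comparisons (2070 and 1605), 106 for NP23 spleen (448), and 6 and 109 for the 2 tissue differences (2 and 323). With a sex term from the Y genes they were 2352 for B-ALL (4208), 7 for NP23 thymus (31), 17 for NP23 spleen (448) and 770 for T-ALL against NP23 thymus (1605); for NP23 thymus and spleen this rests on 1 NP23 array each, and for T-ALL against wild type this rule leaves no sex term, and 2004 genes were called off X and Y. A sex term from Xist gave 1442 there (2070), 2352, 7 and 17 for B-ALL, NP23 thymus and NP23 spleen, 1506 for T-ALL against NP23 thymus and 5317 for the lines (4593), where Hoxd8 turned to -1.52. The Xist term may not stand for sex in T-ALL, where replicates 2 and 3 had low Xist without Eif2s3y or Kdm5d. For B-ALL, NP23 thymus and NP23 spleen both terms marked the same arrays, so the Xist term is no second check. In B-ALL the terms rest on 1 B-ALL array, and in the lines the Xist term rests on 1 line. In T-ALL against NP23 thymus no T-ALL array met the Y rule, so that term only set aside 1 NP23 thymus. NP23 marrow had 2 without its 2 dimmest arrays, with 2 arrays left in each group. NP23 thymus had 16 with the authors' values and 18 with no filter. NP23 spleen had 762 with no background correction, 682 with the authors' values, 902 with median scaling and 138 with no filter. The marrow and thymus difference had 10, 20, 8 and 4 under these 4 settings and 4 with the strict filter, and the thymus and spleen difference 509 and 537 under the first 2 and 131 with no animal block. Up and down splits also moved: 4 and 6 without background correction and 8 and 12 with the authors' values for the marrow and thymus difference (0 and 2). Median scaling shifted the median of all genes to 0.20 for T-ALL against wild type, 0.16 against NP23 thymus, 0.19 for B-ALL, -0.22 for NP23 marrow and -0.23 for the marrow and thymus difference. Adding the lymph node AML samples gave 2491, adding the T-ALL spleen and lymph node samples 1647 and B-ALL from lymph node only 4632. The added T-ALL spleen had Mpo at 15.39 and Cd3e at 7.79 and the added AML node of the same animal Cd3e at 12.24, so these additions may mix cell types. Leaving out 1 array gave 1965 to 3424 for AML, 739 to 2956 for T-ALL and 2334 to 4632 for B-ALL against wild type, 3 to 5, 8 to 59 and 20 to 317 for NP23 marrow, thymus and spleen, and 2718 to 5222 for the lines. It gave 2430 to 3622 for AML against NP23 marrow, 505 to 2393 for T-ALL against NP23 thymus, and 1 to 20 and 66 to 520 for the 2 tissue differences. Leaving out 1 array turned the direction of 4 results called in at least 1 of the 2 fits: primary granule genes in NP23 thymus, -0.25 to 0.61, Hoxd8, T cell lines against wild-type thymus, -1.52 to 4.21, late neutrophil genes in the marrow and thymus difference, -0.33 to 0.33, and Hoxb genes in the thymus and spleen difference, -0.78 to 0.58. The cause was not tested. The Hox differences numbered 9, 2 and 7 without background correction, 9, 2 and 9 with the authors' values and 8, 4 and 8 with median scaling.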

Other observations

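No tests were run for this part, and its values were picked after the results were seen. Brown fat genes were bright in healthy thymus. Ucp1, the uncoupling protein of brown fat, stood at 12.60, 11.35 and 8.71 log2 in wild-type thymus replicates 1, 2 and 3 and at 11.83, 5.66 and 12.03 in NP23 thymus, and Cidea at 13.19, 12.88 and 10.89 and at 12.58, 6.68 and 13.12. The highest T-ALL values were 8.15 for Ucp1 and 9.24 for Cidea, in replicate 7. Single NP23 thymuses also differed in homeobox genes outside the Hoxa cluster: Nkx2-3 stood at 5.81, 11.13 and 11.37 in replicates 1, 2 and 3 against 5.21, 5.01 and 5.54 in wild-type thymus, and Hoxb5 and Hoxb6 at 8.51 and 8.05 in replicate 3. Nkx2-3 was also bright in B-ALL replicates 1, 3 and 4 (12.01, 12.38 and 11.67) and dim in replicate 2 (5.53).

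Hoxb genes varied between leukaemias of 1 kind. Across the 10 AML arrays Hoxb5 ran from 5.28 to 10.76, Hoxb6 from 4.57 to 9.73 and Hoxb9 from 4.54 to 10.06, while Hoxa9 had an SD of 0.15. In B-ALL Hoxb5 ran from 5.69 to 11.61. Arg1 was bright in T-ALL thymus (8.03 to 13.11), in the T-ALL lymph node (11.43) and in AML lymph node replicate 2 (10.63).

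The Y-linked genes did not always move together. AML replicate 5 had Kdm5d at 7.53 and Ddx3y at 11.07 with Eif2s3y at 5.04, and AML replicate 6 had Eif2s3y at 11.22 with Kdm5d at 4.69 and Ddx3y at 9.43, both with low Xist (5.82 and 6.02). The 3 samples of 1 animal, T-ALL replicate 3, the T-ALL lymph node and cell line replicate 2, were low in Xist (5.78, 6.16 and 5.33) and in Eif2s3y (4.45, 4.82 and 4.44).

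The samples outside the comparisons were read as values only. A single animal gave a spleen labelled T-ALL, with the myeloid enzyme gene Mpo at 15.39 and the T cell gene Cd3e at 7.79, and a lymph node labelled AML, with Mpo at 15.12 and Cd3e at 12.24. The lymph node sample titled AML whose disease field reads B-ALL had Mpo at 14.95, Vpreb1 at 5.82, Cd79b at 11.40 and Nkx2-3 at 12.27, and no group was assigned from these. The spleen labelled erythroid had Hbb-b1 at 13.92 and Vpreb1 at 9.76.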
